A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

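Total RNA of Saccharomyces cerevisiae was converted to biotin-labelled cRNA and hybridised to Affymetrix mouse whole-genome arrays, 1 array per preparation and 5 arrays in all. The deposited values are linear probe set intensity, 1 value for each of 45101 probe sets per array. The submitters' processing notes name MAS5 and PLIER without a role, an order or a version, and which of them made the deposited table is not stated. In the table itself every array has a trimmed mean of 150 (2% trimmed at each end), so the authors scaled each array to this target. As a result the total signal of an array carries no information, and a change in the overall background between arrays can be read only relative to the hybridisation spikes, as far as their amount was the same. Values ran from 0.375 to 284336 and 0 of them were zero or negative. Detection calls, scaling factors and probe-level values were not used, so mismatch signal and saturation of single probes could not be examined.

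Probe sets were assigned to mouse genes by the symbol in the array annotation, dated 2016. Of 45037 probe sets other than controls, 34945 had 1 symbol, 932 had several and 9160 had none, and genes were named only from the first kind. Probe sequences and genome positions were not used, so no coordinates are given.

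Intensities were transformed as log2(intensity + 16) and each array was centred on the median of its non-control probe sets. The offset of 16 limits the spread of the lowest values and compresses differences below it. Levels over the array median are on this scale, and folds are 2 raised to it, whereas intensities are given without the offset. All 5 arrays formed 1 group as the labels give it, and no group was available for comparison. High background was tested with an intercept-only model in limma 3.58.1 (R 4.3.3) and its treat function against a 4-fold bound, called upward, and low background against a 2-fold bound, called downward, at a Benjamini-Hochberg adjusted p under 0.05 over 45037 probe sets. The smaller bound was used below because the values have a floor.

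Gene lists were tested with camera in limma, on the mean of the probe sets that name 1 gene, with a preset inter-gene correlation of 0.01 and adjustment over 26 lists, and with an estimated correlation beside it. The lists were 12 families conserved from yeast to mouse, 6 vertebrate families, 7 sets of mouse tissue markers, whose signal would show mouse RNA, and 1 class of clones and predicted genes. Probe set classes were taken from the suffix of the name and compared by the median level per array with an exact sign-flip test over 5 arrays, two-sided, and by Fisher's exact test on the number called. Agreement between arrays was given as Spearman and Pearson correlation across probe sets for 10 pairs and as the share of variance between probe sets. Treatment differences were taken between single arrays as the number of probe sets that differed 4-fold or more, among those at or above the 75th percentile of the mean of the pair.

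The lists, the limma, camera and sign-flip tests, the measures of agreement and of treatment differences, and the rule for named genes were fixed before the data were examined. Fisher's exact tests on the number of probe sets called, in classes, lists and pooled lists, and the shifts of pooled lists were added after the data were seen. The rule named the 25 genes with the highest mean level among probe sets called high that name 1 gene, the control probe sets, up to 4 of the highest members of each list, the 3 genes with the largest difference in each direction for each treatment comparison, and the calcineurin genes. The tests were tried on simulated data with known shifts and the spread of these arrays. Alternatives were offsets of 1 and 64, quantile normalization, bounds of 2-fold and 8-fold, a variance model with a trend and a robust prior, a requirement of the fold in every array with no test, each array left out in turn, other choices of probe sets per gene, and for treatments a 2-fold difference or all probe sets. Figures were drawn with matplotlib 3.10.9.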

Results

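RNA of budding yeast was put on mouse arrays, so that the signal of each mouse probe set could be read in the absence of its intended target. The RNA came from Saccharomyces cerevisiae BY4742, a haploid laboratory strain, and 5 arrays were available, all in 1 group. Each array held a different preparation. In replicate 1 the cells had received amiodarone, an antiarrhythmic drug that also acts on fungi, for 1 h. In replicate 2 the same drug was given for 6 h, and in replicate 3 it was given with calcium and EGTA, a calcium chelator, for 10 min. Replicate 4 came from a strain without CNB1, the regulatory subunit of the calcium-dependent phosphatase calcineurin, after 6 h of amiodarone. Replicate 5 received the solvent DMSO for 1 h. The 5 arrays were therefore not repeats of 1 condition, and every SD below includes the treatments and, for 1 array, the genotype. Each array gave an intensity for 45101 probe sets, of which 64 were controls and 45037 were tested. Of the tested probe sets, 34945 named 1 gene, and these covered 18193 mouse genes. The number of arrays limits the precision of all values.

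The median background intensity of a mouse probe set was 96.5 ± 3.31 (SD, n = 5), on arrays that the authors had scaled to a trimmed mean of 150. The 95th percentile lay at 521 ± 12.5 and the 99th percentile at 951 ± 37.3. Between 346 and 428 probe sets per array, 0.768% to 0.950%, read above 1000, and 5.15% to 5.85% read above 500. The highest intensity of a tested probe set ranged from 74915 to 118849. Averaged over arrays, the distribution had a lower mode near an intensity of 41.5, a trough near 69.8 and an upper mode near 197, at bin counts of 1893 ± 43.8, 1716 ± 54.7 and 2555 ± 73.0 probe sets. Absolute levels cannot be set against arrays of mouse RNA here, because the scaling factors were not used.

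**Figure D1:**
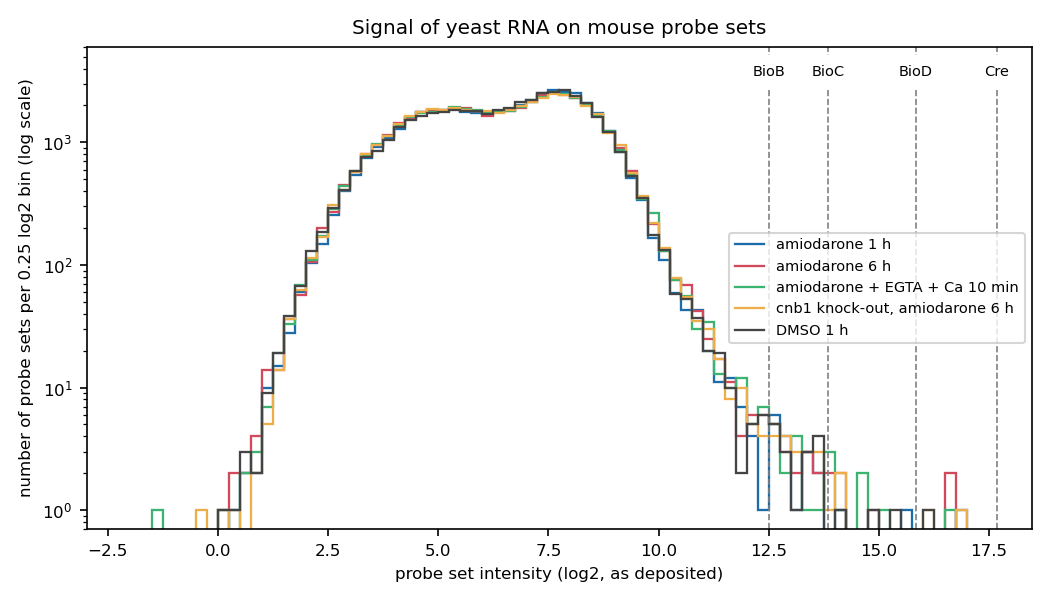
Number of probe sets in each bin of log2 intensity, 1 line per array, with the mean levels of the hybridisation spikes marked for scale. Averaged over the 5 arrays, the lower mode lies near an intensity of 41.5 and the upper mode near 197.

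The control probe sets gave the scale of these values. The bacterial hybridisation spikes, which are added to every sample as labelled RNA, read 5796 ± 643 for BioB, 14758 ± 1313 for BioC, 58487 ± 4398 for BioD and 208537 ± 9267 for the phage gene Cre (geometric mean of each family, SD over n = 5). Over the array median each of these families was highest in the array of amiodarone at 6 h, with BioB at 5.93 against 5.44 to 5.71 in the others and Cre at 10.98 against 10.74 to 10.90. The poly-A spikes, bacterial messages that can be added before labelling, had family means below the array median, although 11 of their 27 probe sets had means above it: Dap at a centred log2 level of -0.32 ± 0.13, Lys at -0.43 ± 0.36, Phe at -0.16 ± 0.25, Thr at -0.08 ± 0.38 and Trpn at -0.93 ± 0.40. Among the controls for mouse transcripts, 18S ribosomal RNA stood highest at 1.71 ± 0.61, an intensity of 372 ± 155. Beta-actin followed at 0.97 ± 0.35 (207 ± 53.4) and Gapdh at 0.86 ± 0.37 (179 ± 40.9). Pyruvate carboxylase read 0.01 ± 0.45, transferrin receptor -0.25 ± 0.33 and the B1/B2 repeat -0.96 ± 0.49. The levels of the controls were not tested against the array median. The weakest probe set of the hybridisation spikes, AFFX-BioB-3_at, had a mean intensity of 4379, and 30 tested probe sets had a higher mean, 17 of them in every array.

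The question the series states, how much background mouse probes bind, was first put to single probe sets. It was asked which of them stood above the typical background, judged by the mean over the arrays. The strongest signal belonged to Rflna (1441881_x_at), with an intensity of 88317 ± 26272 (SD, n = 5), 754-fold over the array median. Gtpbp2 (1448437_a_at), a GTP-binding protein, read 68815 ± 44224, and Shmt1 (1425177_at), the cytosolic serine hydroxymethyltransferase of one-carbon metabolism, read 23788 ± 5105. Hnrnpab (1426114_at), an RNA-binding protein, reached 16655 ± 5582. Pik3cd (1443798_at), a phosphoinositide 3-kinase catalytic subunit of leukocytes, reached 14004 ± 1211. The mean of each was above the mean of the BioB spikes, although Gtpbp2 read 4485 in the array with EGTA and calcium.

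In total, 211 of 45037 probe sets (0.469%) passed a test for a level more than 4-fold over the array median. They had mean intensities from 1092 to 88317, with a median of 1769, and centred log2 levels from 3.30 to 9.56. Of these probe sets 178 named 1 gene, 10 named several and 23 named none, which made 175 genes. The 25 highest genes had levels from 5.34 to 9.56 and adjusted p from 4.76e-05 to 0.00231 (limma). Fam71e1 (1437710_x_at) read 12183 ± 1059, Coro2b (1434326_x_at), a coronin that binds actin, 12279 ± 3131, and Lce1i (1420741_x_at), of the cornified envelope of skin, 10069 ± 725. Next came Sema3f (1438947_x_at), a secreted axon guidance protein, at 10703 ± 4864, and Fen1 (1436454_x_at), the flap endonuclease of DNA replication, at 8955 ± 2822. Crispld2 (1437056_x_at) read 8836 ± 1978. Cdca5 (1416802_a_at), the cohesion factor sororin, read 7878 ± 3791. Adamts16 (1441841_at), a secreted metalloprotease, read 7177 ± 973, and Usp14 (1437714_x_at), a deubiquitinase of the proteasome, 7194 ± 1928. D2hgdh (1437840_s_at), a 2-hydroxyglutarate dehydrogenase, read 7492 ± 3820 and Tff1 (1448156_at), a trefoil peptide of the stomach, 6615 ± 679.

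The remaining genes among the 25 had intensities between 4577 and 7546. Mtg2 (1451467_s_at), a mitochondrial ribosome-associated GTPase, read 6584 ± 555, the predicted gene Gm26910 (1442268_a_at) 7546 ± 5737, and Sppl3 (1451073_at), an intramembrane protease, 6238 ± 1476. Zfp622 (1438000_x_at), a zinc finger protein, read 6038 ± 920. Nfkbia (1420088_at), the inhibitor of NF-kappa-B, read 5571 ± 1037. Sbf2 (1443762_s_at) stood at 5458 ± 720 and Fcgr2b (1435476_a_at), an inhibitory Fc receptor of immune cells, at 5340 ± 1668. Dag1 (1423872_a_at), dystroglycan, stood at 5270 ± 1976 and Pebp1 (1438649_x_at) at 4577 ± 515. For 14 of the 25 genes the highest array was less than 2-fold above the lowest, and for 2 genes the range was over 4-fold. The SD of the level ranged from 0.11 for Lce1i to 1.91 for Gtpbp2.

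**Figure D2:**
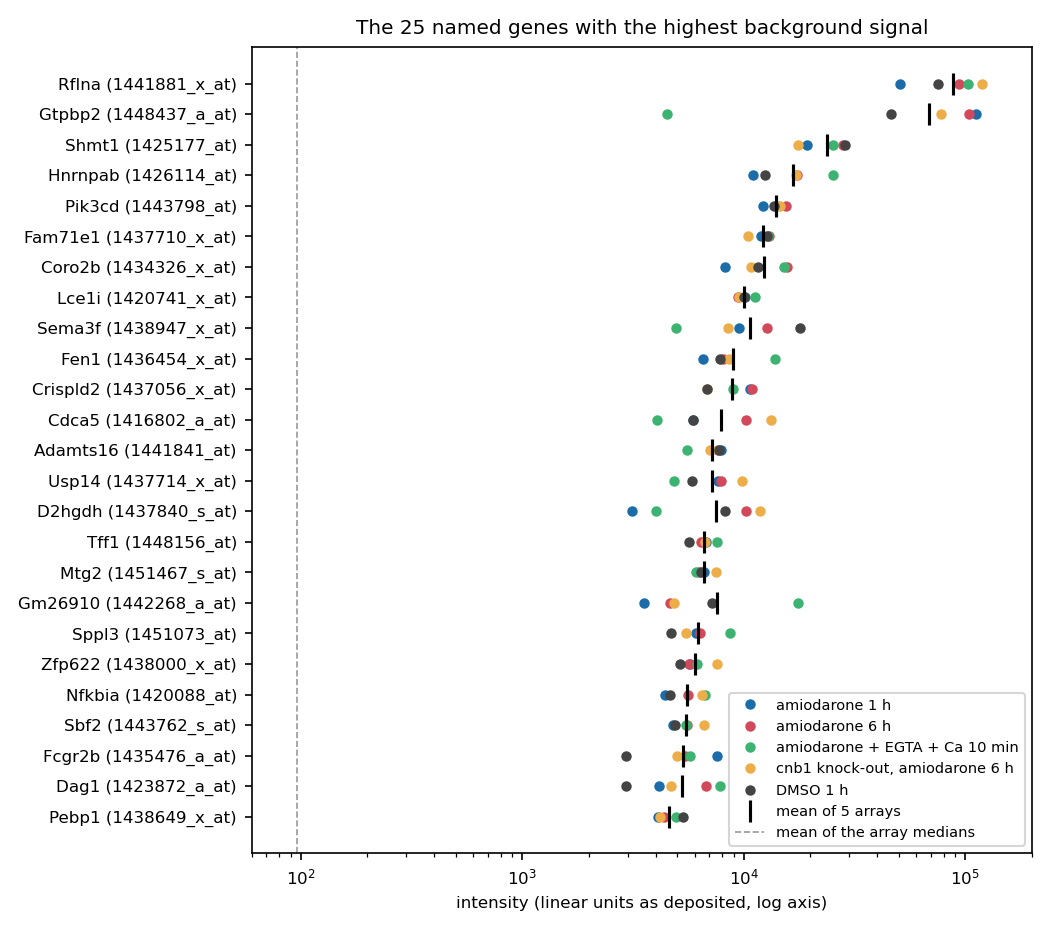
Intensity (log scale) of the 25 genes with the highest background, 1 point per array and a bar for the mean. Rflna and Gtpbp2 stand above the rest, and Gtpbp2 has 1 array at 4485 against 46115 to 111820 in the others.

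Other probe sets of the same genes were read as well. Of the 25 genes, 23 had other probe sets that named them alone, and 0 of these others passed. Over all 175 genes, 3 of 376 other probe sets passed (0.798%, exact 95% interval 0.165% to 2.31%), against 0.509% of all probe sets that named 1 gene. Those genes were Arfgap2, Polrmt and Tpx2, named here after their values were seen. The highest probe set of each gene was left out of the 376, so the 0.509% is not a matched baseline for them.

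The call was strict. In simulated data with the same spread, 0% of 200 probe sets raised 8-fold and 90.5% of those raised 16-fold were found, with 0 false calls. The other simulated probe sets were kept at most 2-fold over the median, so false calls close to the 4-fold bound were not tried. In the arrays themselves 2394 probe sets had a mean 4-fold or more over the median and 1002 had an unadjusted p under 0.05. Any array left out lowered the count of 211, to 116 without replicate 1, 91 without replicate 2, 107 without replicate 3, 96 without replicate 4 and 101 without replicate 5, while a variance model with a trend and robust prior raised it to 754. A level 4-fold or more over the median in every array, with no test, was reached by 1035 probe sets, all 211 among them.

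At the lower end, probe sets with little or no signal were led by Upp2 (1451548_at), a uridine phosphorylase, at an intensity of 3.63 ± 2.09 (SD, n = 5; centred log2 -2.52). Tert (1456941_at), the catalytic subunit of telomerase, read 4.54 ± 3.59, and Zscan21 (1449732_at), a zinc finger protein, 4.72 ± 0.611. Aar2 (1437835_a_at), a splicing factor, read 3.83 ± 1.02, and Fdft1 (1438322_x_at), squalene synthase, 5.43 ± 1.01. These genes were chosen after their values were seen. The test for a level more than 2-fold under the array median passed 732 of 45037 probe sets (1.63%, limma), which covered 555 genes, with mean intensities from 3.63 to 15.6. In simulated data 89% of 200 probe sets lowered 4-fold were found, with 13 false calls. There the other probe sets were kept above the 2-fold bound, so false calls of probe sets at the bound were not tried. In the arrays themselves 3204 probe sets had an unadjusted p under 0.05. The count depended on the offset added before the logarithm, with 2467 probe sets at an offset of 1 and 0 at an offset of 64. Leaving out an array gave 222, 172, 168, 153 and 153 probe sets without replicates 1 to 5, and the trend and robust prior gave 2348.

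The repeatability of the background was then compared between arrays. Among the 25 genes with the strongest background, Lce1i, Fam71e1 and Mtg2 had the smallest SD, 0.11, 0.13 and 0.13 log2 units (n = 5), and D2hgdh, Gm26910 and Gtpbp2 the largest, 0.87, 0.91 and 1.91. Near the median, Ppp3r1 (1421786_at), of the mouse calcineurin regulatory subunit, read between 8.6 and 228. The 14204 probe sets up to 1 log2 unit below the median had a median SD of 1.00, and the 12030 up to 1 unit above it 0.95. It was 0.57 for 6824 probe sets between 1 and 2 units, 0.39 for 1982 between 2 and 3, 0.32 for 311 between 3 and 4, and 0.28 for 87 between 4 and 6. Above 6 units it was higher again, 0.42 for 14 probe sets. Across probe sets, which are not independent replicates, the 10 pairs of arrays had a median Spearman rho of 0.575 (0.556 to 0.587) and a median Pearson r of 0.606. Of the variance, 60.2% lay between probe sets. Among the 11260 probe sets at or above the 75th percentile of the mean level, rho was 0.396 and the share 42.7%. This cut narrows the range of levels, which by itself lowers both, so they do not show that strong background repeats less well.

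**Figure D3:**
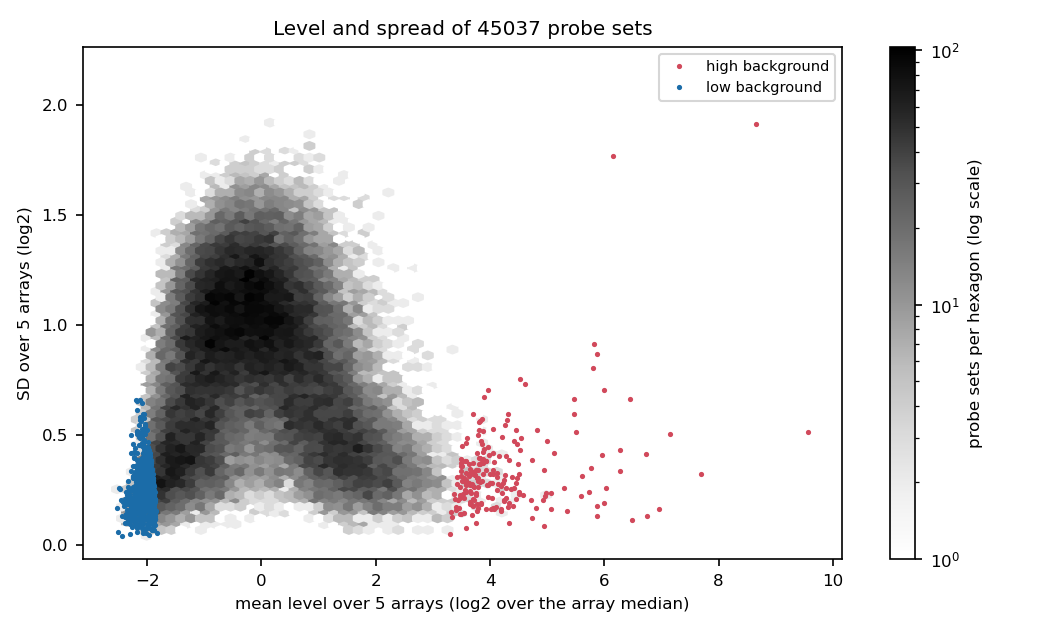
SD of each probe set over the 5 arrays (log2) against its mean level over the array median (log2). The spread is widest around the median, with a median SD of 1.00 just below it, against a median SD of 0.30 for the probe sets called high, of which Gtpbp2 has the largest SD, 1.91. The offset of 16 limits the spread of the lowest levels.

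Gene families that are conserved from yeast to mouse were compared with gene families that are large or specialised in vertebrates and with markers of mouse tissues. Among conserved families, 2 probe sets passed the test for high background. They were Tubb4b (1438622_x_at), a beta-tubulin, at 3784 ± 374 (SD, n = 5, adjusted p = 0.000852, limma), and Atp5d (1456580_s_at), of the mitochondrial ATP synthase, at 2121 ± 441 (adjusted p = 0.00465). In a comparison added after the data were seen, they made 2 of 832 probe sets (0.240%) of 357 genes, with an odds ratio of 0.465 against other named probe sets (95% interval 0.0557 to 1.71, Fisher's exact p = 0.452, two-sided). Vertebrate families had 5 of 1123 (0.445%), an odds ratio of 0.870 (0.278 to 2.08). These were Igk (1425738_at), an immunoglobulin light chain, at 1419 ± 495, the keratin Krt78 (1438849_at) at 1349 ± 211, the collagen Col27a1 (1453191_at) at 1571 ± 322, Zfp59 (1444779_s_at) at 1255 ± 242, and Zfp622, which does have a yeast counterpart, the ribosome biogenesis factor Rei1. Mouse tissue markers had 2 of 229 (0.873%), an odds ratio of 1.73 (0.207 to 6.41): the neuronal kinase Camk2a (1441734_at) at 1501 ± 270 and the leukocyte gene Laptm5 (1447742_at) at 2253 ± 285.

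As whole groups the 357 conserved genes lay -0.06 log2 units from all other genes (95% interval over genes -0.16 to 0.04), the 665 vertebrate genes -0.03 (-0.11 to 0.05) and the 121 tissue markers -0.01 (-0.21 to 0.19). By limma's camera test 0 of 26 lists passed an adjusted p of 0.05, and the smallest adjusted p was 0.0588. At an unadjusted p under 0.05 there were 3 lists, or 2 with an estimated correlation between genes. Fisher's exact test of the number of high probe sets gave 0 lists at an unadjusted p under 0.05, and that of low probe sets gave 2 unadjusted and 0 adjusted. Adjusted over the list alone, 7 probe sets of conserved lists were high and 33 low, against 2 and 21 over all probe sets. For vertebrate lists the counts adjusted over the list alone were 5 and 26, against 5 and 24, and for tissue lists 4 and 17, against 2 and 8. In simulated data 3 of 3 lists shifted 2-fold were found, with 0 false calls among the other lists. The 3 shifted lists had 46, 38 and 42 genes, and the shift was larger than that of any list above. Smaller shifts and smaller lists, such as calcineurin with 5 genes, were not tried, so the power to find them is not known.

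The list of chaperones, which fold proteins, had the lowest mean shift among conserved families, -0.60 ± 0.09 (SD over n = 5 arrays), and was below other genes in all 5 arrays, but did not pass (adjusted p = 0.0588, and adjusted p = 0.444 with an estimated correlation). Of its 73 probe sets 5 were low, for Hspa4, Cct8, Cct7, Hspa8 and Cct3, at intensities of 9.46, 11.3, 11.6, 12.5 and 14.9, and 0 were high. Their share gave an odds ratio of 4.50 (adjusted p = 0.0952, Fisher's exact test). Cct6a, a chaperonin subunit, had the highest level of the list at 954 ± 182 and did not pass. Olfactory receptors, expressed in the nose, had a shift of 0.55 ± 0.13, above other genes in 5 of 5 arrays, and did not pass either (adjusted p = 0.0588, and adjusted p = 0.444 with an estimated correlation). Their 43 probe sets were neither high nor low, and Olfr15 (1422372_at) read 716 ± 143. Without replicate 4 both lists passed, at -0.64 and 0.60 (adjusted p = 0.0491), and also at an offset of 1, at -0.77 and 0.67 (adjusted p = 0.0390). With the highest probe set of each gene the shifts were smaller, -0.33 for chaperones (adjusted p = 0.585) and 0.16 for olfactory receptors (adjusted p = 0.603), and at an offset of 64 they were -0.40 and 0.39 (adjusted p = 0.145). Taking the highest probe set favours lists with many probe sets per gene. Chaperones had 73 for 25 genes, olfactory receptors 43 for 38, and all named genes 34945 for 18193. These 2 smaller shifts can therefore follow from the choice itself. Over all alternatives the adjusted p ranged from 0.0390 to 0.585 for chaperones and from 0.0390 to 0.603 for olfactory receptors.

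The shifts of the other conserved families did not pass. Glycolysis lay at 0.38 (95% interval over genes -0.25 to 1.01), with the pyruvate kinase Pklr at 656 ± 124, and actins and tubulins at 0.36 (-0.14 to 0.85), with cardiac actin Actc1 at 625 ± 170. Calcineurin lay at 0.33 (-0.36 to 1.02), and each of these families was above other genes in 5 of 5 arrays. For calcineurin the shift ranged from 0.0008 in DMSO to 0.71 in the CNB1 knock-out. The same probe sets are read on every array, so agreement in sign over arrays is no separate support for the shift of any list. Proton ATPases lay at 0.11 and electron transport at 0.03. Cytosolic ribosomal proteins lay at -0.06, and their highest member, Rpl38 (1433472_x_at), read 1462 ± 523 and missed the threshold (adjusted p = 0.0556). The proteasome and ubiquitin list lay at -0.10, with the ubiquitin-conjugating enzyme Cdc34 at 905 ± 549. Translation factors lay at -0.10, with Eif3c at 1958 ± 922 (adjusted p = 0.0949) and the elongation factor Eef1a1 at 728 ± 170. RNA polymerases and splicing proteins lay at -0.11, with the splicing factor Sf3b4 at 1618 ± 704 (adjusted p = 0.0544). Core histones lay at -0.13, with H2ac19 at 493 ± 173, and small GTPases and signalling at -0.18, with the casein kinase Csnk1d at 1629 ± 801 (adjusted p = 0.195).

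Among vertebrate families, collagens lay at 0.29, keratins at 0.21, cytokines and chemokines at 0.05, and immunoglobulins, T-cell receptors and MHC at -0.25 (95% interval over genes -0.47 to -0.02). The 356 zinc finger genes lay at -0.18 (-0.28 to -0.08), with 2 high and 20 low of 660 probe sets, and the low share gave an odds ratio of 1.93 (adjusted p = 0.0952, Fisher's exact test). The chemokine Ccl4 read 858 ± 77.9. Among tissue markers, liver lay at 0.28, brain at 0.23, leukocyte at 0.20, muscle at -0.00, fibroblast at -0.08, testis at -0.29 and erythroid at -0.73 (-1.38 to -0.09, adjusted p = 0.213). The haemoglobin gene Hba-a1 read 85.4 ± 65.6 and the liver gene Apoc3 544 ± 121, and neither passed. RIKEN clones and predicted genes lay at -0.10 (-0.15 to -0.05), with 10 high of 2331 probe sets and 6 when adjusted over the list alone, led by Gm26910. The immunoglobulin, zinc finger, erythroid and RIKEN lists were above other genes in 0 of 5 arrays, and their intervals over genes excluded 0. By camera, which is a different calculation, their unadjusted p was 0.184, 0.148, 0.0246 and 0.377, and none passed after adjustment. For cytokines and chemokines the mean and the test pointed up and the median (-0.03) down. The signs of core histones, cytokines, ribosomal proteins, electron transport, RNA polymerases and splicing, small GTPases, translation factors, keratins, liver, fibroblast and muscle turned under at least 1 alternative.

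**Figure D4:**
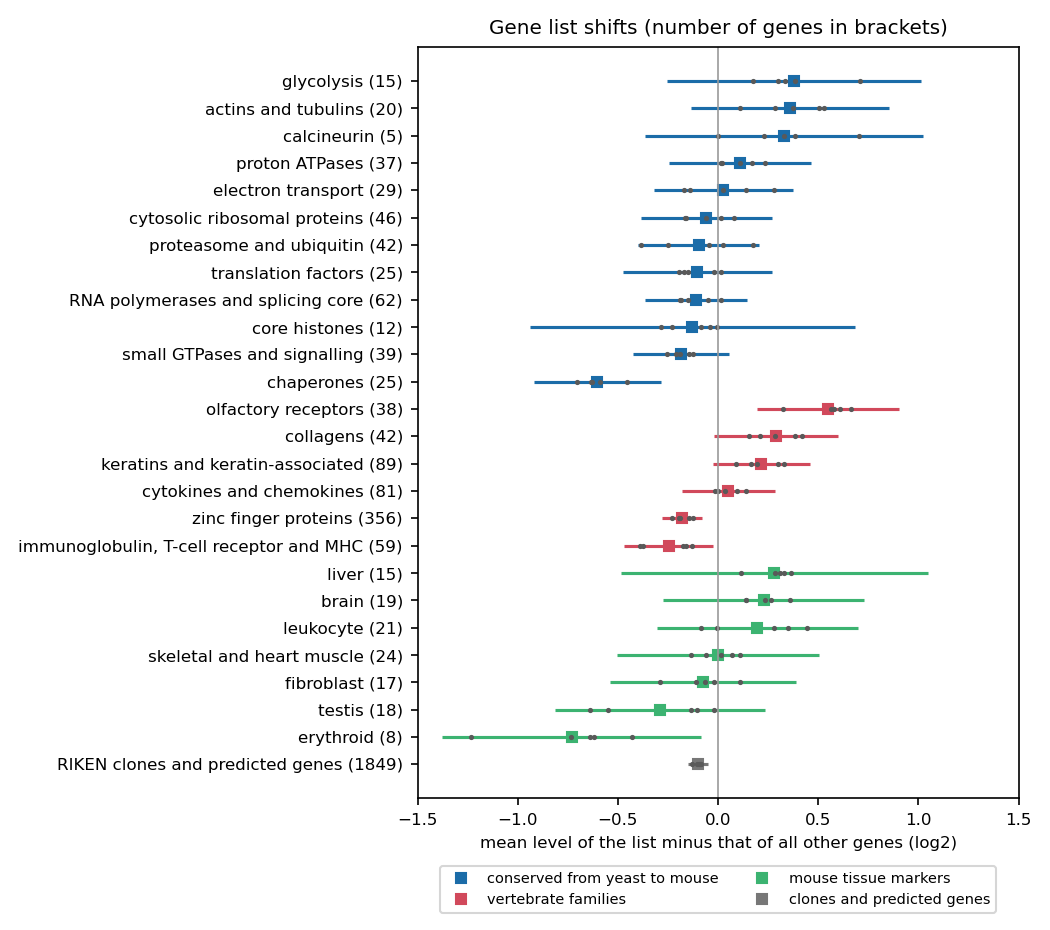
Mean level of each gene list minus that of all other genes (log2), with a bar for the 95% interval over genes (unadjusted) and a point per array. Chaperones (-0.60) and erythroid markers (-0.73) lie lowest and olfactory receptors (0.55) highest, and none passed the adjusted test.

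The mouse calcineurin genes were read because 1 yeast strain lacked the yeast regulatory subunit. Of their 13 probe sets 0 were high and 0 were low (limma). Ppp3r1 (1433591_at), the mouse regulatory subunit, had the highest mean, 631 ± 57.3 (SD, n = 5), with 665 in the knock-out and 685 in its counterpart after 6 h of amiodarone. The other Ppp3r1 probe set, 1421786_at, read 193 in the knock-out and 124 in that counterpart. The highest probe sets of the catalytic subunits were Ppp3ca (1438478_a_at) at 341 ± 151 and Ppp3cb (1427468_at) at 288 ± 177. For Ppp3cc, 1430025_at read 166 ± 123, and the other regulatory gene, Ppp3r2 (1437535_at), read 118 ± 78.0. The array was made for mouse genes, and binding of yeast CNB1 to these probe sets was not tested, so these values cannot check the genotype.

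Affymetrix marks probe sets whose probes match several transcripts by a suffix, and these classes were compared with the ordinary _at class. The _x_at class, whose probes can bind unrelated transcripts, held Rflna, Fam71e1, Coro2b, Lce1i, Sema3f, Fen1, Crispld2, Usp14, Zfp622 and Pebp1, or 10 of the 25 highest genes, against 7 of the _at class. Among 2441 _x_at probe sets 49 were high (2.01%), compared with 115 of 36082 _at probe sets (0.319%), an odds ratio of 6.41 (p = 1.66e-20, Fisher's exact test, two-sided). By the same exact test the _s_at class had 20 of 2088 (0.958%, odds ratio 3.02, p = 4.7e-05) and the _a_at class 27 of 4426 (0.610%, odds ratio 1.92, p = 0.00418). The same classes held more low probe sets, 3.44% for _x_at, 2.78% for _s_at and 2.03% for _a_at against 1.39% for _at, with odds ratios of 2.54, 2.03 and 1.48. The median level of the _x_at class was below that of the _at class by -0.35 ± 0.05 log2 units (SD, n = 5), of _s_at by -0.19 ± 0.03 and of _a_at by -0.13 ± 0.04. Each difference was negative in 5 of 5 arrays, with an exact sign-flip p = 0.063, the smallest that 5 arrays allow. Probe sets of 1 gene are not independent, so the Fisher values describe probe sets and not separate experiments. The size of the odds ratio of 6.41 also depended on the call, from 1.57 at a 2-fold bound to 14.9 at an 8-fold bound.

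Treatments were compared between single arrays, with no test because each condition had 1 array. After 1 h of amiodarone relative to DMSO, the probe sets of Abcc9, a subunit of potassium channels, Rassf1 and Ttll10 were higher by 3.45, 3.41 and 3.34 log2 units. Those of Chmp4b, an ESCRT protein, Adam1b and Obsl1 differed by -3.80, -3.51 and -3.49. Among the 11260 probe sets at or above the 75th percentile of the mean of the pair, 119 were 4-fold or more higher and 140 lower (2.30%). For amiodarone at 6 h relative to 1 h, Cmah, which makes a sialic acid, Fam98c and Rgs14 were higher by 3.76, 3.72 and 3.63, and Cypt3, Phip and Lin7b differed by -4.22, -3.77 and -3.52, with 221 probe sets higher and 123 lower (3.06%). After quantile normalization these counts were 189 and 163.

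In the CNB1 knock-out relative to BY4742, both after 6 h of amiodarone, Marchf5, a mitochondrial ubiquitin ligase, Lrpap1 and Kmt2c were higher by 3.92, 3.72 and 3.54. Strbp, Pi4k2a and Tmem158 differed by -3.76, -3.53 and -3.43, and 191 probe sets were higher and 174 lower (3.24%). For amiodarone with EGTA and calcium at 10 min relative to DMSO at 1 h, where the times differ too, Polr2a, the large subunit of RNA polymerase II, Cela3b and Sox12 were higher by 4.26, 3.81 and 3.70. E2f5, Baz1b and Gtpbp2 differed by -4.16, -3.35 and -3.27, and 169 probe sets were higher and 121 lower (2.58%). After quantile normalization the balance turned, with 139 higher and 154 lower. It also turned for amiodarone at 1 h relative to DMSO when all probe sets (3095 higher, 3016 lower) or a 2-fold difference (985 and 944) were taken, and for the knock-out with all probe sets (3088 and 3137). Among the 11260 probe sets with the highest mean in each pair, the 10 pairs of arrays had between 2.18% and 3.58% 4-fold apart. On the same probe sets the SD of the differences lay between 0.78 and 0.85 log2 units. These shares do not cover all probe sets. The median difference of the probe sets compared was 0.11 for 6 h relative to 1 h and 0.12 for EGTA with calcium relative to DMSO. Among the 211 probe sets with high background, 0, 1, 1 and 1 differed 4-fold in these comparisons, in the order given. These are intensities of mouse probe sets in yeast RNA and say nothing of the mouse genes themselves.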

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

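The tests in this part were written down before their results were seen. For 90 values the array farthest from the others was compared with the whole range of the 5 arrays, and 8 values had a gap above 0.71 of the range. Chance gives about 1 in 20, or 4.5 of 90, so single cases below can be chance.

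The probe set of Gtpbp2 (1448437_a_at) had a gap of 0.717 of its range, with a level of 5.35 in the array of amiodarone with EGTA and calcium against 8.63 to 9.92 in the others. Scaling of the whole array could not be tested, because centring each array on its own median removes it from all probe sets alike. On the centred values the 210 other probe sets with high background had a median difference of 0.18 between this array and DMSO. Their 5th to 95th percentile ran from -0.68 to 1.03, so they did not drop together. A yeast transcript that binds this probe set and is lower after this treatment may account for the difference of -3.27 from DMSO. With 1 array per condition this cannot be told apart from a chance fault of 1 array.

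Of the other strong probe sets, Lce1i had a gap of 0.895, from a level of 6.68 in the array with EGTA and calcium against 6.42 to 6.45. Mtg2 had a gap of 0.845, from a level of 6.10 in the CNB1 knock-out against 5.79 to 5.84. Adamts16 had a gap of 0.770, from a level of 5.66 in the array with EGTA and calcium against 6.01 to 6.11. The Ppp3r1 probe set 1421786_at had a gap of 0.778, from a level of -2.25 in DMSO against 0.34 to 1.08. Among the controls, the poly-A spike Dap had a gap of 0.776, from a level of -0.09 in the CNB1 knock-out against -0.40 to -0.33. The mouse Gapdh control had a gap of 0.723, from a level of 0.23 in DMSO against 0.90 to 1.16. The transferrin receptor control had a gap of 0.729, from a level of -0.83 in DMSO against -0.22 to 0.01.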

How the results depend on the processing

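The alternatives for the odds ratio of the _x_at class were chosen after the data were seen, and the other alternatives before. All 25 named genes stayed past the threshold under 12 settings (300 of 300 values), and the odds ratio stayed past it, between 1.57 (2-fold bound) and 14.9 (8-fold bound), with 2.38 when every array had to pass the fold and 3.41 with trend and robust prior. No paired analysis was possible because the arrays form 1 group. Some settings change counts by construction: the bounds, the larger set of probe sets, and the rule for every array, which has no test. Fewer arrays lower the power of the limma tests on probe sets. A larger offset compresses low levels, so fewer probe sets can lie 2-fold under the median. With a trend the expected spread follows the level, and the median SD was 1.00 just below the median but 0.28 between 4 and 6 log2 units above it. How much of each change this explains was not tested. High probe sets, 211 in the report, numbered 2468 at a 2-fold bound, 41 at an 8-fold bound, 754 with trend and robust prior (210 of the 211 among them) and 1035 when every array had to pass the fold, and 91 to 116 with 1 array left out. Low probe sets, 732 in the report, numbered 2467 at an offset of 1, 0 at 64, 2348 with trend and robust prior, 2603 when every array had to pass, and 153 to 222 with 1 array left out. Gene lists past the threshold, 0 in the report, numbered 2 at an offset of 1, 1 with the highest probe set of each gene (RIKEN clones and predicted genes at -0.431, adjusted p = 0.0106), and 0 to 2 with 1 array left out. The smallest adjusted p over these settings ranged from 0.0106 to 0.444. Taking the highest probe set of each gene also moves lists by construction, because the highest of more probe sets tends to be higher. The RIKEN list had 2331 probe sets for 1849 genes, against 34945 for 18193 over all named genes, which by itself lowers its shift.

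Counts of treatment differences followed the settings. For amiodarone 1 h relative to DMSO, 6 h relative to 1 h, EGTA and calcium relative to DMSO and the knock-out relative to BY4742, in that order, an offset of 64 gave 70, 135, 104 and 112 higher and 77, 56, 63 and 94 lower. Quantile normalization gave 134, 189, 139 and 163 higher and 164, 163, 154 and 160 lower. Taking all probe sets gave 3095, 3305, 3066 and 3088 higher and 3016, 3112, 2714 and 3137 lower. A 2-fold difference gave 985, 1308, 1261 and 1107 higher and 944, 848, 784 and 1033 lower. The larger of the higher and lower counts changed sides for EGTA and calcium with quantile normalization, for 1 h relative to DMSO with all probe sets and at 2-fold, and for the knock-out with all probe sets. At or above the 75th percentile of the level, rho was 0.396 and the variance between probe sets 42.7%. The class differences from _at at an offset of 64 were -0.0937 for _a_at, -0.132 for _s_at and -0.237 for _x_at, and -0.409 for _x_at at an offset of 1.

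Of 286 list shifts 266 kept sign and side, 5 passed the threshold and 15 changed sign, none of these past the threshold. With the highest probe set of each gene the sign turned for cytokines (-0.192), ribosomal proteins (0.0646), fibroblast (0.0363), keratins (-0.107), liver (-0.0923), RNA polymerases and splicing (0.0306), small GTPases (0.362) and translation factors (0.311). That choice favours lists with many probe sets per gene, so these turns can follow from the number of probe sets. With _at and _a_at probe sets only it turned for core histones (0.0412) and muscle (0.0751), and at an offset of 64 for muscle (0.0121). With 1 array left out electron transport ranged from -0.0365 to 0.0754 and muscle from -0.0281 to 0.0330. The depth of an array is its signal over background, and levels near the median, with a median SD of 1.00, are the least certain.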

Other observations

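The test of the mean level of _x_at probe sets, the test of conserved families and the test of variance between genes in all classes of probe sets were chosen after the results were seen. Several genes had more than 1 probe set at the same end of the scale, and these were picked out after their values were seen. Of all probe sets that named 1 gene, 0.509% were high and 1.62% low. The number of such genes that independent calls would give was not worked out, so they do not show binding shared within a gene. Polrmt, the mitochondrial RNA polymerase, read 2085 (1452835_a_at) and 1881 (1437377_a_at; mean intensity, n = 5). Tpx2, a spindle protein, read 1941 (1447518_at) and 1654 (1447519_x_at), and Arfgap2, of Golgi transport, 1695 (1447228_at) and 1158 (1447229_x_at). The last 2 genes each have neighbouring identifiers, and whether such probe sets share sequence was not examined. At the low end, 2 of the 6 probe sets of the RNA helicase Ddx5 read 6.18 ± 3.32 and 12.7 ± 11.3. For the small heat shock protein Cryab 2 of 3 probe sets read 10.5 ± 4.38 and 14.1 ± 4.21, and for Eloc, elongin C, 2 of 4 read 6.14 ± 3.10 and 8.59 ± 5.13. For Ugcg, glucosylceramide synthase, 2 of 4 read 10.8 ± 6.88 and 12.4 ± 4.25, and for Rbm25, a splicing regulator, 2 of 6 read 10.8 ± 7.12 and 13.6 ± 9.46. After Gtpbp2, the widest spread among the 211 high probe sets was that of 1415895_at, which names several genes (SD 1.76), followed by Gm26910 (0.91) and D2hgdh (0.87), against a median SD of 0.30.

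For the over-representation of the _x_at class among probe sets with high background, a narrower spread that makes such probe sets easier to call is argued against as the whole cause by the mean level alone, since the odds ratio of a mean 16-fold or more over the array median was 7.29 (95% interval 4.22 to 12.3). It may still be part of the excess at 4-fold, where the odds ratio was 6.41 with the test but 2.38 when every array had to pass the fold with no test, and 3.41 with trend and robust prior. Repeated counting of 1 gene is argued against by a draw of 1 probe set per gene, 15503 probe sets, with an odds ratio of 12.03 (6.84 to 20.7). Probes that bind many transcripts may carry this excess, although the suffix does not say whether they bind yeast RNA. By itself this would not give the excess of low _x_at probe sets (odds ratio 2.54) or their lower median level (-0.35 ± 0.05 log2 units). Probe sequences were not compared, and neither this nor a biological explanation was tested.

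By this call, high background was mostly attached to single probe sets: 3 of 376 other probe sets of the same genes passed, those of Polrmt, Tpx2 and Arfgap2. The call found 0% of simulated probe sets raised 8-fold, so the count does not exclude lesser rises in the others. Binding shared by all probe sets of a gene would place much of the variance between genes, but with _at and _a_at probe sets 3.58% lay between 7906 genes, against -1.97% to 2.35% in shuffled data. With all classes it was 4.39% between 9010 genes (-2.01% to 2.27% in shuffled data), so over all these genes a shared part was present but small. Only 0.509% of the probe sets that named 1 gene were high, so these shares cannot decide the cause of the high ones. In the genes with a high probe set, the 376 others had a median level of -0.04, against -0.08 for all probe sets that named 1 gene. With the highest of each gene left out, these others were not raised as a group. Homology of the yeast transcript to the mouse gene may contribute: the odds ratio of the conserved families was 0.465, from 2 probe sets, with an interval (0.0557 to 1.71) that includes 1, and the genes compared with them include some with yeast counterparts, such as Shmt1, Fen1 and Zfp622, so this stayed open. A short match of a few probes to an unrelated yeast transcript stays open too, as no sequences were compared.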
